A study of Mus musculus with 12 samples.

How the data were processed

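RNA of 12 colon tumours induced with azoxymethane in FvB mice was measured by RNA sequencing, 3 libraries for each of the genotypes wt, miR-34a deficient, p53 deficient and double deficient in intestinal epithelial cells. Per the labels, total RNA was isolated with a QIAGEN kit and libraries followed standard Illumina protocols. The authors deposited score values, that is, normalized expression values per gene symbol rounded to whole numbers; the genome build is mm10 per the submitters' processing notes. The aligner, counting, annotation and normalization are not given in the sources used here. The plan assumed counts, and the values showed otherwise. Upper quartiles lay between 1905 and 1982.25 and median-of-ratios factors between 0.975 and 1.06 in all libraries. The deviations of the libraries from their genotype means spanned 7 dimensions where 8 were expected (seventh singular value 32.2, last 0.179, over 9791 genes with a mean of at least 500). A direction of variation within genotypes is therefore absent from the deposited values. Of its squared weights 47.2% lay on double deficient 3, 16.5% on double deficient 2 and at most 7.94% on any other library. The missing spread thus falls mainly on the double deficient group. Tests that need counts were not used, and the depth and counting precision of each library are unknown.

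Values were taken as log2 of the value plus 1, with no rescaling. Of 21792 genes, 21322 with a mean value of at least 1 were tested with limma 3.58.1 in R 4.3.3 (moderated t test with a trend in the prior variance), with 1 mean per genotype, all 12 libraries and 8 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 count as changed. The comparisons were each deletion against wt, double against each single deletion, and the interaction of the 2 deletions; p53 against miR-34a deficient tumours was added after the data were examined. The labels do not state whether replicates are separate animals, so p-values measure the spread between these samples. Replicate numbers were not treated as pairs, since 4 of 18 same-number pairs correlated above 0.1 and 5 of 12 libraries lay closest to their own number.

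The 36 gene lists, the test, the comparisons, the alternatives listed first below and the genes to name were chosen before the data were examined. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Beside it stand camera with an estimated correlation and the number of members passing when adjusted over the list alone. Directional fry was run on every list and kept 8 of the 84 list calls, losing 76. Its values are printed only for some of the lists that it called. The matching of older and newer gene symbols to the lists was corrected after results were seen. Lists share genes: all 27 core p53 targets are in the wider p53 list, and Wnt target genes and intestinal stem cell markers share 6. A list's median, mean and test differed in sign in 24 of 216 list results, none of them called (lowest camera adjusted p 0.435). Genes with a miR-34a seed site (8mer or 7mer-m8) in an annotated 3' untranslated region of GENCODE M21 (GRCm38) were tested against the other genes with such a region by camera. Positions were found for 20809 of 21322 genes (97.6%).

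The genes named are the deleted genes and Vil1, the genes fixed in every comparison (among them Il6ra, Axl, Inhbb, Cdkn1a, Mdm2, Ccng1, Il6, Socs3, Lgr5, Axin2, Vim, Cdh1, Mki67 and Myc), the 10 largest changes in each direction and the list members with the smallest p. The largest changes were taken among changed genes with a mean log2 of at least 1 per 1e6 of the column sum, a gene symbol that is not a clone name, and no overlap between the groups compared. Where fewer than 5 passed in a direction, the 5 with the smallest p are given as values. Results of some genes are left out of the text and of the counts of named calls.

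The procedure was tested on simulated data with the spread of these libraries and 200 changed genes, in 10 simulations of double deficient against wt. With 1 direction removed, as in the deposited values, the 8 degree of freedom fit recovered 35.8%, 76.1% and 94.7% of genes changed by 1, 2 and 4 on the log2 scale, and 11.3% of its calls were false. A fit with the removed direction as a covariate, on 7 degrees of freedom, recovered 30.1%, 70.6% and 92.7% with 4.95% false. Its count is therefore given for the total of changed genes in each comparison. The counts of list members, of genes near the loci and of genes shared between sets come from the 8 degree of freedom fit alone. Lists of 30 genes shifted by 0.5 were called in 20 of 20 runs and unshifted lists in 0 of 20, at unadjusted camera p under 0.05. These runs drew each gene independently and removed no direction. They therefore cannot show how often lists of correlated genes are called falsely.

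The alternatives were median-of-ratios, upper-quartile and quantile rescaling, pseudocounts of 0.1 and 5, other filters on low values, only the groups compared, a replicate block, the run code as a covariate or its libraries left out, an adjusted p under 0.10 and leaving out each library. Added after seeing the data were the removed direction and the Y-linked level as covariates and leaving out genes on chromosomes X and Y. Library weights were tried too, but their estimation stopped early, so no fit used them. Where an omission leaves 2 libraries in a group, the spread is pooled over all groups.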

Results

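Total RNA from colon tumours of FvB mice was sequenced after treatment with azoxymethane (AOM), a carcinogen that gives rise to colon tumours. The mice had received 10 mg/kg by weekly injection over 6 weeks, and the experiment ended at week 16 after the first dose. The 12 libraries fall into 4 genotypes with 3 libraries each. These are wt, tumours lacking miR-34a in intestinal epithelial cells (miR-34a deficient), tumours lacking p53 in those cells (p53 deficient), and tumours lacking both (double deficient). Values are normalized scores per gene, not read counts, so the depth of each library is unknown. Column sums ranged from 45310209 to 101121673 and do not measure depth, since the X-linked RNA Xist alone made up 52.8% of the sum in miR-34a deficient 1 and 23.2% in wt 1. Of 21792 genes in the table, 95 were 0 in every library and 21322 were tested. Changes are log2 differences of group means ± SE with n = 3 libraries per genotype.

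The libraries also differed in ways the genotype labels do not give. The mean log2 level of 4 Y-linked genes was 0 in wt 1 and miR-34a deficient 1, between 0.25 and 0.79 in the 3 double deficient libraries, and between 2.77 and 6.98 in the other 7. Every p53 deficient library therefore lay above every double deficient library on this measure. Xist made up 5.92%, 4.52% and 1.24% of the sum in double deficient 1, 2 and 3, and at most 0.00958% in p53 deficient libraries. It made up at most 0.234% in wt 2 and 3 and miR-34a deficient 2 and 3. Double deficient libraries thus lay apart from these on both measures. The comparisons of double deficient tumours with wt and with miR-34a deficient tumours may carry part of that difference too. The library names carry a run code, which differs for miR-34a deficient 1 and p53 deficient 1 from that of the other 10. The mean log2 level of 6 posterior Hox genes was 8.40 in p53 deficient 2 and between 11.7 and 15.6 in the other 11. In the 6 comparisons below, the counts of changed genes and the calls of named genes and lists were also computed with the Y-linked level as a covariate, chosen after seeing the data, without the 2 libraries of the other run code, and without each library.

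The deleted genes were read in every library first. Trp53, the gene of p53 (ENSMUSG00000059552; GRCm38 chromosome 11, 69580359 to 69591873), had values of 4512, 4305 and 4126 in wt tumours and of 4357, 3466 and 5120 in miR-34a deficient tumours. It had values of 598, 401 and 576 in p53 deficient and of 924, 504 and 724 in double deficient tumours. Trp53 fell by 3.06 ± 0.24 on the log2 scale in p53 deficient tumours against wt (adjusted p = 0.000753), which is 8.33 times. It fell by 2.63 ± 0.24 in double deficient tumours against wt (adjusted p = 0.000623) and by 2.61 ± 0.24 against miR-34a deficient tumours (adjusted p = 0.000668). Mir34a (chromosome 4, 150068454 to 150068555) is not in the table, so the loss of the microRNA could not be read from these values. Vil1, the gene of villin in the brush border, passed no test against wt, with log2 changes of -0.11, -0.01 and -0.14 (each ± 0.22) in miR-34a, p53 and double deficient tumours.

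**Figure D1:**
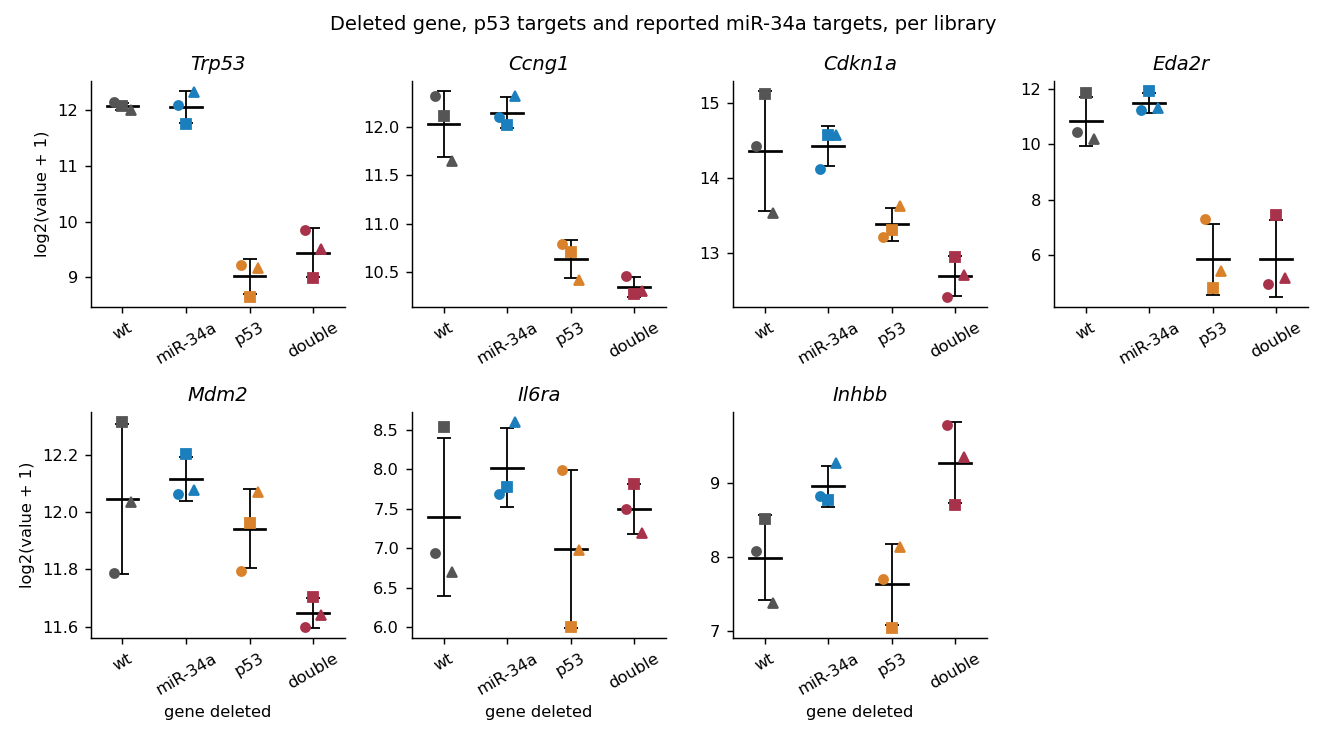
Expression of Trp53, Ccng1, Cdkn1a, Eda2r, Mdm2, Il6ra and Inhbb as log2 of the normalized value plus 1 (vertical axis) in the 4 genotypes (horizontal axis); each point is a library, its shape gives the replicate number, and bars show the group mean with its SD (n = 3). Trp53 lies near a value of 4512 in wt 1 and at or below 924 in all 6 p53 and double deficient libraries, and Eda2r at or below 174 in the same 6 libraries.

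Deletion of miR-34a alone changed few genes in these tumours. The glycolytic enzyme gene Eno1 (chromosome 4, 150236721 to 150248879) rose by 0.93 ± 0.13 (adjusted p = 0.0468); it lies 0.168 Mb from Mir34a. Its near-identical copy Eno1b on chromosome 18 had values of 19469, 16386 and 14333 in wt and of 85, 135 and 71 in miR-34a deficient tumours, and fell by 7.46 ± 0.27 (adjusted p = 1.83e-07). The ribosomal protein gene Rpl35a rose by 3.15 ± 0.23 (adjusted p = 0.000265). Reads of such genes can be shared with their copies and pseudogenes, so these values are uncertain.

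**Figure D2:**
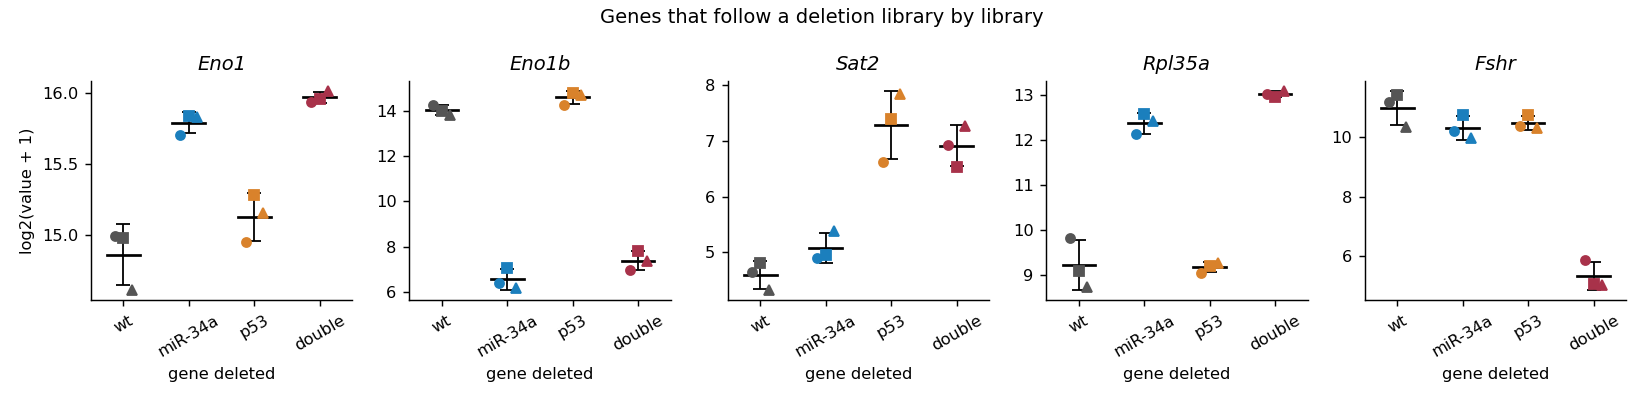
Expression of Eno1, Eno1b, Sat2, Rpl35a and Fshr as log2 of the normalized value plus 1 (vertical axis) in the 4 genotypes (horizontal axis), with a point per library and bars for the mean and SD (n = 3). Eno1b lies between 71 and 225 in the 6 libraries lacking miR-34a and between 14333 and 28557 in the other 6, while Fshr lies between 32 and 58 in double deficient libraries only.

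The genes named in advance did not pass in miR-34a deficient tumours. Il6ra, the interleukin-6 receptor and a published miR-34a target, had a log2 difference of 0.63 ± 0.55 (adjusted p = 0.934). Inhbb, an activin subunit, was at 0.96 ± 0.37 (adjusted p = 0.766). Those of Vim, the mesenchymal filament gene, and the cell cycle inhibitor Cdkn1a were 0.68 ± 0.29 and 0.06 ± 0.32. None of 63 published miR-34a targets passed limma's test over all genes or adjusted over the list alone, and their median was 0.12 (camera adjusted p = 0.358). Genes with a miR-34a seed site in the 3' untranslated region (2598 of 16625 genes with an annotated one) had a median 0.04 above genes without a site (camera adjusted p = 0.263 over the 2 comparisons tested), and 0.02 above genes matched for length of that region. The other fixed genes Axl (0.35 ± 0.35), Mdm2 (0.07 ± 0.14), Ccng1 (0.12 ± 0.18), Il6 (-0.59 ± 0.88), Socs3 (0.12 ± 0.34), Lgr5 (-0.30 ± 0.67), Axin2 (0.53 ± 0.39), Cdh1 (-0.03 ± 0.14), Mki67 (-0.09 ± 0.26) and Myc (-0.17 ± 0.18) did not pass either. Outside the fixed genes, Ceacam2 at 2.23 ± 0.33 was among the closest to passing (adjusted p = 0.0601). St8sia2 (2.33 ± 0.38), Clstn1 (1.20 ± 0.20), Dnah8 (1.43 ± 0.24), Tlcd2 (-0.79 ± 0.14), Rnf157 (-1.96 ± 0.35), Xaf1 (-2.49 ± 0.47), Hopx (-0.62 ± 0.13) and Cenph (-1.02 ± 0.21) followed without passing.

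Cell type and growth lists were nevertheless called by camera at the preset correlation. Neither camera with an estimated correlation nor directional fry called any list in this comparison, so a shift of whole groups is not established. The proliferation list lay lower, with 35 of 37 members below 0 and a median of -0.40, and 9 at unadjusted p under 0.05 (camera adjusted p = 4.67e-14). All 18 endothelial markers lay above 0 with a median of 0.92, and 14 had an unadjusted p under 0.05 (camera adjusted p = 3.59e-12). With an estimated correlation neither call held, with adjusted p = 0.674 and adjusted p = 0.587. Smooth muscle markers (median 0.63, all 18 above 0), fibroblast and matrix genes (0.46) and EMT and mesenchymal genes (0.45) also lay higher, with camera adjusted p = 6.52e-07, 0.000304 and 0.000304; adjusted p = 0.674, 0.764 and 0.764 with an estimated correlation. Plasminogen activation (median 0.94) and Wnt target genes (0.55) lay higher with camera adjusted p = 0.0159 and 0.0211; adjusted p = 0.764 and 0.788 with an estimated correlation. Colonocyte (median -0.50), goblet (-0.40), epithelial junction (-0.16) and fetal or regenerative epithelium genes (-0.28) lay lower, with camera adjusted p = 0.000756, 0.0134, 0.00231 and 0.000798. For these 4 lists adjusted p = 0.764, 0.833, 0.587 and 0.135 with an estimated correlation. DNA repair (-0.20), immediate early (-0.42), interferon response (-0.37) and inflammatory genes (-0.38) lay lower too, with camera adjusted p = 0.000232, 0.000339, 0.00231 and 0.00703; adjusted p = 0.764, 0.764, 0.803 and 0.788 with an estimated correlation. In none of these 15 lists did a member pass limma's test over all genes, and adjusted over the list alone only 2 endothelial genes passed. Among lists that were not called, the hypoxia list held Eno1, which rose, at a median of -0.12 (camera adjusted p = 0.428).

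By limma's test 8 of 21322 genes changed in miR-34a deficient tumours, 3 higher and 5 lower, against 1299 at unadjusted p under 0.05. The groups did not overlap for 10.1% of genes, where chance gives 10%. Other changed genes, named after their values were seen, were the pseudogenes Gm19791 (3.50 ± 0.48), Gm4735 (-7.06 ± 0.66) and Gm9825 (-1.27 ± 0.15) and the clone 3110043O21Rik (-1.01 ± 0.14). Rpl35a and Eno1b passed under all 26 alternatives, but Eno1 under 3 (adjusted p up to 0.351). The count was 4 without wt 1 or wt 3, 5 without miR-34a deficient 3, p53 deficient 1 or double deficient 3. It was also 5 with quantile normalization, the removed direction or the Y-linked level as a covariate. Lists were lost without wt 1 (4 lists, adjusted p up to 0.236), wt 2 (inflammatory genes, 0.832) and wt 3 (5 lists, up to 0.680). They were also lost without miR-34a deficient 1 (inflammatory genes, 0.196), 2 (3 lists, up to 0.127) and 3 (4 lists, up to 0.254). Goblet cell markers were also lost with quantile normalization (adjusted p = 0.0502), and Wnt target genes and immediate early genes with the run code as a covariate (0.0801 and 0.0753). Inflammatory cytokines and chemokines were lost without the libraries of the other run code (0.207).

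In p53 deficient tumours 2 of 27 core p53 targets passed as lower. Ccng1, cyclin G1 (chromosome 11, 40748552 to 40755311), fell by 1.40 ± 0.18 (adjusted p = 0.0368), and 9030617O03Rik, the p53 target also named Dglucy, fell by 2.05 ± 0.26 (adjusted p = 0.0368). Fam212b fell by 3.80 ± 0.39 (adjusted p = 0.00781). Sat2 (chromosome 11, 69622024 to 69623870), which lies 0.0417 Mb from Trp53 and was named after its value was seen, rose by 2.70 ± 0.36 (adjusted p = 0.0378). The death receptor gene Eda2r at -4.99 ± 0.74 (adjusted p = 0.0604) and the epoxide hydrolase gene Ephx1 at -3.38 ± 0.56 (adjusted p = 0.0684), both p53 targets, did not pass.

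Of 27 core p53 target genes 2 fell and 25 did not pass over all genes; 12 fell when adjusted over the list alone. Their median was -0.40 (camera adjusted p = 3.41e-07; adjusted p = 0.486 with an estimated correlation; fry adjusted p = 0.0295). Of the wider list of 61 p53 targets, which holds the core list, 2 fell, 10 fell when adjusted over the list alone, and the median was -0.27 (camera adjusted p = 3.03e-06; adjusted p = 0.486 with an estimated correlation). Cdkn1a had a log2 difference of -0.98 ± 0.32 (adjusted p = 0.197) and Mdm2, whose product degrades p53, of -0.10 ± 0.14 (adjusted p = 0.768). The cytokine gene Il6 was at 1.05 ± 0.88 (adjusted p = 0.598), Il6ra at -0.40 ± 0.55 and Vim at -1.01 ± 0.29 (adjusted p = 0.152). Axl (-0.53 ± 0.35), Inhbb (-0.36 ± 0.37), Socs3 (0.34 ± 0.34), Lgr5 (-1.24 ± 0.67), Axin2 (-0.68 ± 0.39), Cdh1 (0.06 ± 0.14), Mki67 (0.62 ± 0.26) and Myc (0.38 ± 0.18) did not pass. Nor did Galk1 (1.49 ± 0.23), Ftsj3 (1.07 ± 0.17), Tceal8 (1.49 ± 0.24), Lrrk2 (0.95 ± 0.16), Mybbp1a (0.93 ± 0.16), Sbspon (-1.84 ± 0.27), Tead2 (-1.30 ± 0.19) or Tsga10 (-1.71 ± 0.28), which came closest.

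Camera at the preset correlation also called metabolic and growth lists in p53 deficient tumours. No member passed limma's test over all genes in any of the lists that follow. Of 25 hypoxia and glycolysis genes 24 lay above 0, with a median of 0.54, 9 at unadjusted p under 0.05 and 3 passing when adjusted over the list alone (camera adjusted p = 2.84e-08). All 13 mitochondrially encoded genes lay below 0 with a median of -0.59, and 6 had an unadjusted p under 0.05 (camera adjusted p = 7.51e-05). Proliferation (median 0.24) and cytosolic ribosomal protein genes (0.17) lay higher, with camera adjusted p = 0.000218 and 0.00366. Wnt target genes had a median of -0.96, and adjusted over the list alone 10 of 26 were lower and 2 higher (camera adjusted p = 0.00575). This call was lost without p53 deficient 2 (adjusted p = 0.0608), the library with the low posterior Hox level, where Wif1 was at 449 against 1793 and 914 in the other 2. Colonocyte (-0.75), goblet (-0.75), macrophage and monocyte (-0.75) and mast cell markers (-1.03) lay lower, with camera adjusted p = 0.00243, 0.0338, 0.00589 and 0.0329. Neutrophil markers (0.76) and plasminogen activation genes (0.67) lay higher, with camera adjusted p = 0.0124 and 0.0241. Every list in this paragraph had adjusted p = 0.855 with an estimated correlation. Adjusted over the list alone, 2 goblet markers were lower, 1 plasminogen activation gene was higher, and no other member of the last 8 lists apart from the Wnt targets passed.

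In all, 5 of 21322 genes changed in p53 deficient tumours by limma's test, 1 higher and 4 lower, against 3265 at unadjusted p under 0.05. The groups did not overlap for 16.2% of genes (chance gives 10%). Trp53 alone passed under all 26 alternatives; Fam212b passed under 23, Ccng1 under 10 (adjusted p up to 0.301) and 9030617O03Rik under 9. The count was 88 without p53 deficient 1, 14 without wt 3, 1 without wt 1, and 2 or 3 without any other library except wt 2, where it was 4. It was 8 without the 2 libraries of the other run code, 2 with the removed direction and 1 with the Y-linked level as a covariate, 2 with a replicate block and 1 with only the 2 groups in the fit. With the Y-linked covariate the calls of proliferation genes, plasminogen activation, colonocyte markers, goblet cell markers, macrophage and monocyte markers, neutrophil markers and mast cell markers were lost (adjusted p between 0.0759 and 0.280). Omitting wt 1 ended 5 list calls (adjusted p up to 0.270), wt 2 ended 3 (up to 0.147) and wt 3 ended 4 (up to 0.324). Omitting p53 deficient 1, 2 and 3 ended 3, 4 and 2 (up to 0.149, 0.755 and 0.0667). Without the 2 libraries of the other run code the plasminogen, goblet and neutrophil calls were lost (adjusted p up to 0.142).

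Tumours lacking both miR-34a and p53 showed low markers of the differentiated colon epithelium. The goblet cell gene Retnlb fell by 7.86 ± 0.96 (adjusted p = 0.00394), from values of 5662, 4796 and 10451 in wt to 12, 95 and 17. Aqp8, a water channel of surface colonocytes, fell by 6.54 ± 0.84 (adjusted p = 0.00589), from 298, 238 and 249 to 0, 10 and 1. The chloride and bicarbonate exchanger Slc26a3 fell by 4.95 ± 0.92 (adjusted p = 0.0371). The endothelial genes Cdh5 and Flt1, a cadherin and a VEGF receptor, rose by 2.01 ± 0.38 and 1.89 ± 0.33 (adjusted p = 0.0371 and 0.0323).

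Of 32 colonocyte markers 7 fell and 25 did not pass; adjusted over the list alone 21 fell and 1 rose. The 7 were Aqp8, Slc26a3, the carbonic anhydrase Car4 (-3.78 ± 0.73), Saa1 (-3.85 ± 0.64), Guca2a (-3.09 ± 0.57), Tmigd1 (-2.68 ± 0.50) and the protease Mep1b (-2.41 ± 0.47). Of these 7 only Aqp8 passed with the removed direction as a covariate, and only Aqp8 without double deficient 3. The list's median was -1.87 (camera adjusted p = 8.30e-16; adjusted p = 0.225 with an estimated correlation; fry adjusted p = 0.0215). Of 20 goblet markers Retnlb and Clca3 (-4.33 ± 0.74) fell, 11 fell when adjusted over the list alone, and the median was -1.79 (camera adjusted p = 5.42e-11; adjusted p = 0.377 with an estimated correlation). Under the same settings, the removed direction as a covariate or double deficient 3 left out, Retnlb passed and Clca3 did not. Epithelial junction genes, which all epithelial cells express, had a median of -0.22 with 0 of 22 passing over all genes or adjusted over the list alone and 5 at unadjusted p under 0.05 (camera adjusted p = 0.00913; adjusted p = 0.377 with an estimated correlation). The median of 20 enteroendocrine markers was -0.38, with 2 lower when adjusted over the list alone (camera adjusted p = 0.0262; adjusted p = 0.733 with an estimated correlation). Paneth-type markers (median 0.62) were not called (camera adjusted p = 0.893); their member Pla2g2a fell by 4.54 ± 0.80.

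**Figure D3:**
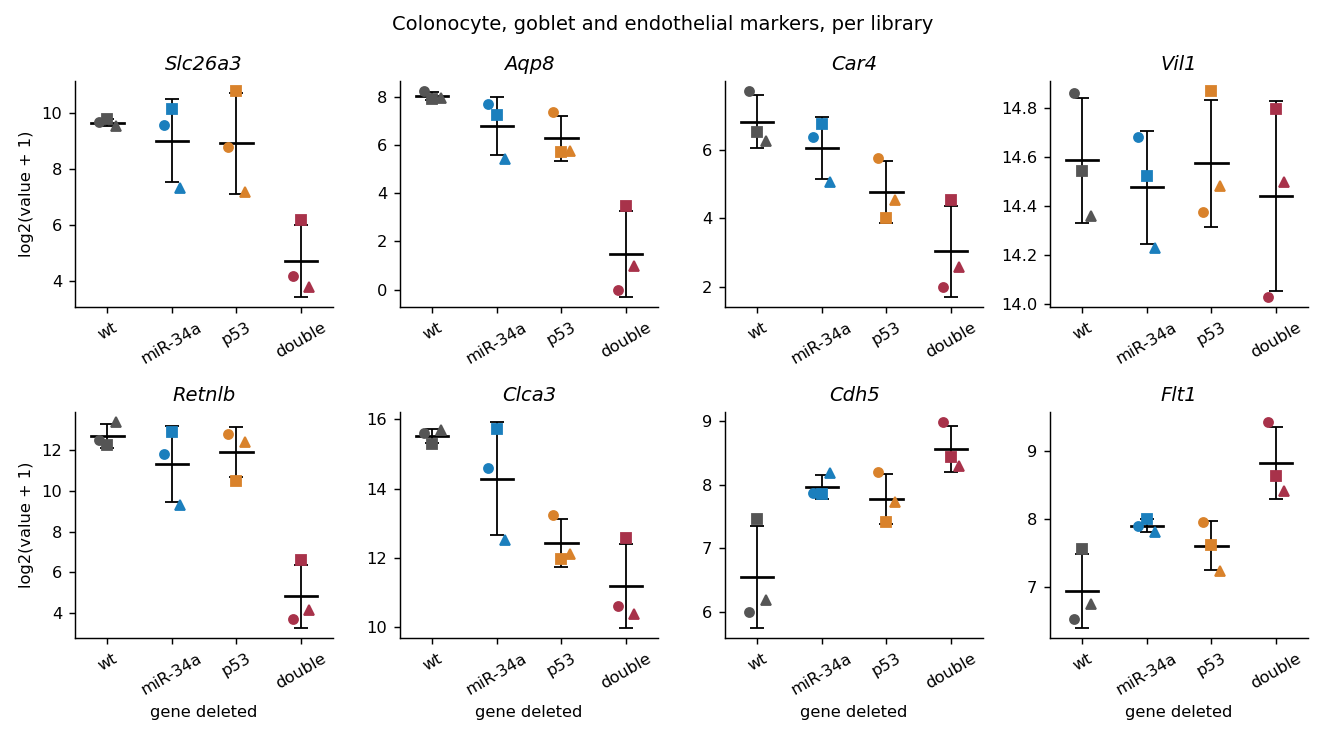
Expression of Slc26a3, Aqp8, Car4, Vil1, Retnlb, Clca3, Cdh5 and Flt1 as log2 of the normalized value plus 1 (vertical axis) in the 4 genotypes (horizontal axis), with a point per library and bars for the mean and SD (n = 3). Aqp8 lies at 0, 10 and 1 in double deficient libraries and at 42 or above in the other 9, and Retnlb lies at 12, 95 and 17 and at 621 or above.

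The p53 targets were lower in double deficient tumours as well. Of 27 core targets 8 fell, among them Cdkn1a (-1.68 ± 0.32, adjusted p = 0.0439), Ccng1 (-1.69 ± 0.18, adjusted p = 0.00200), Eda2r (-4.97 ± 0.74, adjusted p = 0.0156) and Ephx1 (-3.14 ± 0.56, adjusted p = 0.0323). Adjusted over the list alone 16 fell and 1 rose, 26 of 27 lay below 0, and the median was -0.81 (camera adjusted p = 5.03e-15; adjusted p = 0.118 with an estimated correlation; fry adjusted p = 0.00345). The wider list had 8 of 61 lower, 17 adjusted over the list alone, and a median of -0.46 (camera adjusted p = 5.42e-11; adjusted p = 0.127 with an estimated correlation). Mdm2 was at -0.40 ± 0.14 (adjusted p = 0.212).

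Some vessel, glycolysis and neutrophil genes rose, and no list named here was called with an estimated correlation. All 18 endothelial markers lay above 0 with a median of 0.99; Cdh5 and Flt1 rose, and 13 rose when adjusted over the list alone (camera adjusted p = 5.42e-11; adjusted p = 0.377 with an estimated correlation). Of 25 hypoxia and glycolysis genes Eno1 (1.11 ± 0.13) and the lactate exporter gene Slc16a3 (2.0 ± 0.39) rose, 7 rose when adjusted over the list alone, and the median was 0.54 (camera adjusted p = 1.08e-08; adjusted p = 0.377 with an estimated correlation). Of 18 neutrophil markers Ngp (3.41 ± 0.64) and Retnlg (5.57 ± 1.11) rose and Ly6g (-1.52 ± 0.30) fell. Adjusted over the list alone 7 rose and 1 fell, with a median of 2.0 (camera adjusted p = 1.62e-05; adjusted p = 0.387 with an estimated correlation). Retnlg was at 0, 1 and 0 in the wt libraries and at 86, 73 and 32 in the double deficient ones, and Ngp at 1, 1 and 0 and at 22, 12 and 15. Values this near the floor make both changes depend on the pseudocount, and with 0.1 neither passed (Ngp 5.01, adjusted p = 0.169; Retnlg 8.04, adjusted p = 0.112). The 15 plasminogen activation genes had a median of 1.13 (camera adjusted p = 0.000189; adjusted p = 0.377 with an estimated correlation). Inflammatory genes had a median of 0.99, with 0 of 26 passing limma's test over all genes, 7 higher at unadjusted p under 0.05 and 3 higher when adjusted over the list alone (camera adjusted p = 0.000131; adjusted p = 0.632 with an estimated correlation). Il6 was at 3.15 ± 0.88 (adjusted p = 0.129), Inhbb at 1.28 ± 0.37 (adjusted p = 0.143) and Il6ra at 0.11 ± 0.55 (adjusted p = 0.954). The iron uptake gene Tfrc rose by 1.90 ± 0.21 (adjusted p = 0.00283), the endothelial peptide gene Apln by 2.85 ± 0.44 and the transthyretin gene Ttr by 4.02 ± 0.64. Ctla2a (1.91 ± 0.37) and Apobec3 (1.85 ± 0.31) rose as well. The fixed genes Axl (0.03 ± 0.35), Socs3 (0.60 ± 0.34), Lgr5 (0.41 ± 0.67), Axin2 (0.19 ± 0.39), Vim (-0.28 ± 0.29), Cdh1 (-0.12 ± 0.14), Mki67 (0.34 ± 0.26) and Myc (0.43 ± 0.18) did not pass.

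A further 6 lists were called, with no member passing limma's test over all genes. Mitochondrially encoded genes had a median of -0.59, with all 13 below 0 and 5 at unadjusted p under 0.05 (camera adjusted p = 2.63e-05; adjusted p = 0.632 with an estimated correlation). Proliferation (0.28), cholesterol synthesis (0.30), DNA repair (0.22) and mast cell genes (1.00) lay higher, and immediate early genes (-0.32) lower, with camera adjusted p = 0.000306, 0.00573, 0.0262, 0.0299 and 0.0209. Each of these 5 had adjusted p = 0.733 with an estimated correlation, and adjusted over the list alone only 2 immediate early genes passed. Published miR-34a targets had a median of 0.06, with 5 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.190). IL6-STAT3 genes had a median of 0.32 (camera adjusted p = 0.0741), and of their 36 members only Mcl1, a survival gene, fell (-0.70 ± 0.12). Enteric nerve and glia markers (median -0.09), T and NK cell markers (0.52), B and plasma cell markers (-0.12), adipocyte markers (0.12), MHC class II genes (-0.10) and senescence and SASP genes (0.33) were not called, with camera adjusted p = 0.955, 0.0723, 0.893, 0.451, 0.881 and 0.168. Intestinal stem cell markers (0.04) were not called here either (camera adjusted p = 0.741).

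**Figure D4:**
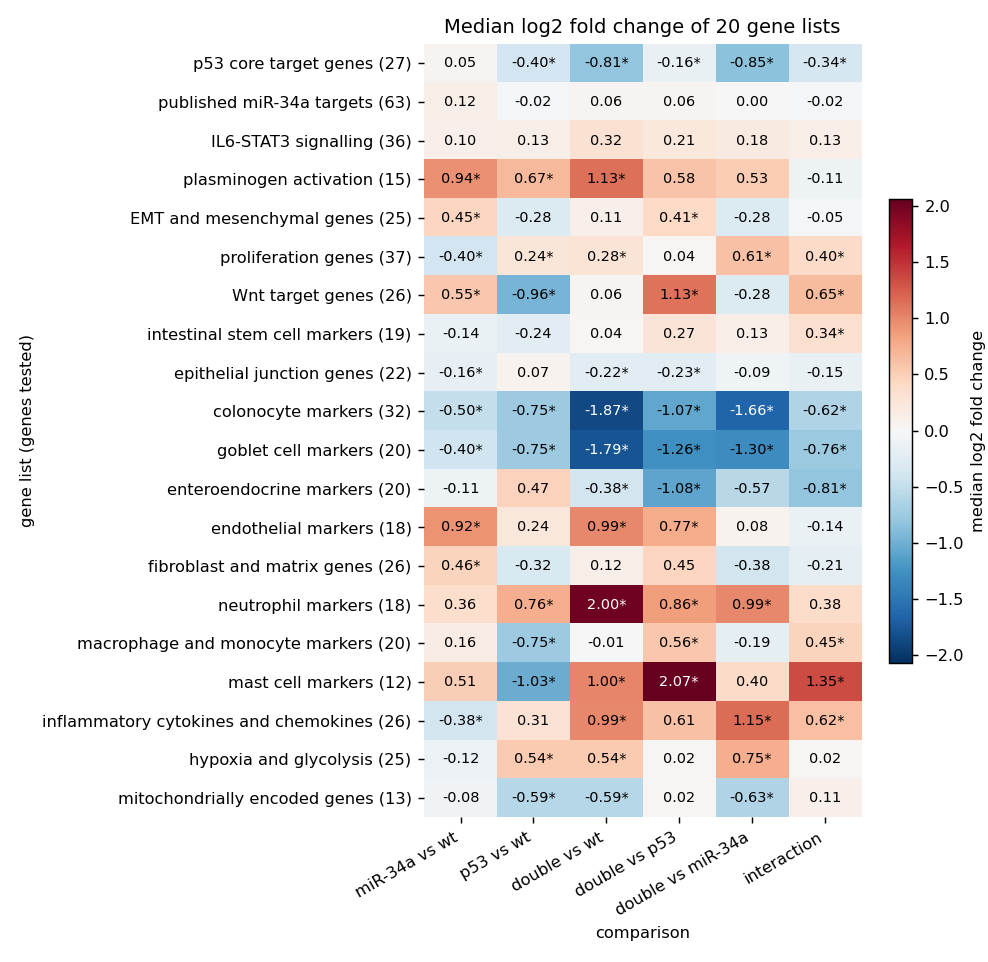
Median log2 change of the members of 20 fixed gene lists (vertical axis) in the 6 comparisons (horizontal axis), shown as colour with the value printed in each cell; an asterisk marks camera adjusted p under 0.05, and none of the calls held with an estimated correlation. The colonocyte list is at -1.87 and the endothelial list at 0.99 in double deficient tumours against wt.

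In double deficient tumours 171 of 21322 genes changed against wt by limma's test, 47 higher and 124 lower, and the groups did not overlap for 19.8% of genes (chance gives 10%). Among the genes with the largest changes were also Fshr, the FSH receptor gene (-5.64 ± 0.32), Rpl35a (3.80 ± 0.23), Eno1b (-6.62 ± 0.27), the proton pump gene Atp12a (-4.59 ± 0.68), Fer1l6 (-4.98 ± 1.00) and Rpl3-ps1 (-4.91 ± 0.90), of which Rpl35a, Eno1b and Rpl3-ps1 have near-identical copies. Under all 26 alternatives 10 of the 38 named calls passed, namely Trp53, Ccng1, 9030617O03Rik, Aqp8, Retnlb, Fshr, Tfrc, Eno1, Eno1b and Rpl35a. Cdkn1a passed under 11 (adjusted p up to 0.171) and Cdh5 under 12 (up to 0.133). Of the 38, 10 passed without double deficient 3, 11 without wt 1, 12 without double deficient 1 and 16 without wt 3. The count of changed genes was 29 without double deficient 3, 42 without wt 1 or double deficient 1, 59 without wt 3, 97 without miR-34a deficient 1 and 261 without p53 deficient 2. It was 57 with the removed direction and 80 with the Y-linked level as a covariate, 88 with only the 2 groups in the fit, 102 with a replicate block and 74 without the libraries of the other run code. Without wt 1 the junction, proliferation and DNA repair calls were lost (adjusted p up to 0.0823), and without wt 2 the proliferation, DNA repair, cholesterol and immediate early calls (up to 0.604). Without wt 3 the enteroendocrine and mast cell calls were lost (up to 0.393), as they were with the junction call without double deficient 1 (up to 0.559). Without double deficient 2 the cholesterol and immediate early calls were lost (up to 0.290), and without double deficient 3 DNA repair (0.0960). Quantile normalization ended the junction (0.244) and mitochondrial (0.0862) calls, and the Y-linked covariate the mast cell, cholesterol and immediate early calls (up to 0.0785).

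Double deficient tumours were then compared with p53 deficient tumours, which asks what loss of miR-34a adds where p53 is absent. Retnlb fell by 7.09 ± 0.96 (adjusted p = 0.00854) and Aqp8 fell by 4.79 ± 0.84 (adjusted p = 0.0327); at double deficient values of 0, 10 and 1 it did not pass with a pseudocount of 0.1 (adjusted p = 0.0656). Gsta1, a detoxifying glutathione transferase, fell by 2.96 ± 0.35 (adjusted p = 0.00360), and Atp12a fell by 4.92 ± 0.68 (adjusted p = 0.00940). Sbspon rose by 1.92 ± 0.27 (adjusted p = 0.00941) and Ttr by 3.81 ± 0.64 (adjusted p = 0.0290). Aif1l (3.00 ± 0.55), Cpn1 (2.82 ± 0.51), Lmcd1 (2.20 ± 0.42), Cib2 (2.12 ± 0.40), Pde3b (2.07 ± 0.39), Rem2 (1.95 ± 0.31) and Nrros (1.94 ± 0.30) rose, and Csta1 (-3.50 ± 0.52), Abat (-3.03 ± 0.55), Adamts15 (-2.97 ± 0.52) and Fam129a (-2.18 ± 0.36) fell. All 3 p53 deficient libraries lay above the 3 double deficient ones in Y-linked level, so every value of this comparison carries that difference too.

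Of 32 colonocyte markers only Aqp8 fell over all genes; adjusted over the list alone 10 fell and 1 rose, and the median was -1.07 (camera adjusted p = 2.83e-08; adjusted p = 0.720 with an estimated correlation). Of 20 goblet markers Retnlb fell, 2 fell when adjusted over the list alone, and the median was -1.26 (camera adjusted p = 4.27e-06; adjusted p = 0.720 with an estimated correlation). All 18 endothelial markers lay above 0 with a median of 0.77, with 0 passing limma's test over all genes or adjusted over the list alone and 9 at unadjusted p under 0.05 (camera adjusted p = 2.00e-06; adjusted p = 0.720 with an estimated correlation). Wnt target genes had a median of 1.13 and mast cell markers of 2.07. No member passed over all genes, while adjusted over the list alone 11 of 26 and 8 of 12 were higher (camera adjusted p = 5.16e-06 and 2.65e-05; adjusted p = 0.720 for both with an estimated correlation). The Wnt call held without each library, p53 deficient 2 included (adjusted p up to 0.000453). All 15 tuft cell markers lay above 0 with a median of 1.41, and macrophage and monocyte markers had a median of 0.56, with 4 higher at unadjusted p under 0.05 in each list and 0 passing limma's test over all genes or adjusted over the list alone (camera adjusted p = 0.00244 for both; adjusted p = 0.810 for both with an estimated correlation). Neutrophil markers had a median of 0.86 while their member Ly6g fell by 2.43 ± 0.30, and adjusted over the list alone 1 rose and 1 fell (camera adjusted p = 0.0256; adjusted p = 0.810 with an estimated correlation).

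Epithelial junction (median -0.23) and enteroendocrine genes (-1.08) lay lower, each with camera adjusted p = 0.000238; adjusted p = 0.479 and 0.720 with an estimated correlation. No member passed over all genes, and 2 and 4 were lower when adjusted over the list alone. Of the immediate early genes (median -0.72) the transcription factor gene Klf6 fell by 1.47 ± 0.18, also when adjusted over the list alone (camera adjusted p = 0.00176; adjusted p = 0.810 with an estimated correlation). Of the fetal or regenerative genes (-0.20) Anxa3 fell by 0.78 ± 0.14, and adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 0.0320; adjusted p = 0.479 with an estimated correlation). EMT and mesenchymal genes (0.41) lay higher and core p53 targets (-0.16) lower, each with camera adjusted p = 0.0152; adjusted p = 0.892 and 0.773 with an estimated correlation. Adjusted over the list alone 1 EMT gene was higher and 3 core p53 targets were lower, and none passed over all genes. Published miR-34a targets had a median of 0.06 (camera adjusted p = 0.509), and genes with a miR-34a seed site lay -0.03 from those without a site (camera adjusted p = 0.425). Il6ra was at 0.51 ± 0.55 (adjusted p = 0.700), Inhbb at 1.64 ± 0.37 (adjusted p = 0.0835) and Il6 at 2.10 ± 0.88 (adjusted p = 0.285). Axl (0.56 ± 0.35), Cdkn1a (-0.69 ± 0.32), Mdm2 (-0.29 ± 0.14), Ccng1 (-0.29 ± 0.18), Socs3 (0.26 ± 0.34), Lgr5 (1.65 ± 0.67), Axin2 (0.87 ± 0.39), Vim (0.74 ± 0.29), Cdh1 (-0.19 ± 0.14), Mki67 (-0.28 ± 0.26) and Myc (0.06 ± 0.18) did not pass.

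By limma's test 129 of 21322 genes changed between double deficient and p53 deficient tumours, 48 higher and 81 lower, and the groups did not overlap for 19.6% of genes (chance gives 10%). With the Y-linked level as a covariate the count was 7, and with only the 2 groups in the fit it was 12. The count was 47 with the removed direction as a covariate. It was 27 without double deficient 3, 37 without double deficient 1, 51 and 60 without p53 deficient 2 and 3, 79 without miR-34a deficient 1 and 294 without p53 deficient 1. Of 24 named calls only those of Eno1b (-7.19 ± 0.27), Fshr (-5.13 ± 0.32) and Rpl35a (3.84 ± 0.23) passed under all 26 alternatives, and only those 3 passed with the Y-linked covariate or with only the 2 groups in the fit. Of the 24, 7 passed without double deficient 1 or double deficient 3, 9 without p53 deficient 3 and 12 without p53 deficient 2. The Y-linked covariate ended the fetal, tuft, macrophage and immediate early calls (adjusted p up to 0.177), and quantile normalization the junction and fetal calls (0.0734 and 0.215). The run code as a covariate ended that of neutrophil markers (0.0510). Without p53 deficient 2 the calls of 5 lists were lost (adjusted p up to 0.331), and without p53 deficient 3 that of EMT genes (0.0977). The same held without double deficient 1 those of EMT, tuft and macrophage genes (up to 0.324), without double deficient 2 those of fetal and neutrophil genes (up to 0.165) and without double deficient 3 that of fetal genes (0.0546).

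Against miR-34a deficient tumours, where the comparison asks what loss of p53 adds when miR-34a is absent, double deficient tumours had lower p53 targets. Cdkn1a (-1.74 ± 0.32, adjusted p = 0.0354), Ccng1 (-1.81 ± 0.18, adjusted p = 0.00120), Eda2r (-5.65 ± 0.74, adjusted p = 0.00775) and Fam212b (-3.85 ± 0.39, adjusted p = 0.00137) fell. The proliferation gene Cdc20 (0.77 ± 0.16, adjusted p = 0.0492) rose, and so did, among the largest changes, Cdkn3 (1.22 ± 0.23) and the spindle checkpoint gene Bub3 (1.21 ± 0.23). Slc16a3 rose by 2.44 ± 0.39 (adjusted p = 0.0194), Tfrc by 1.86 ± 0.21 (adjusted p = 0.00299) and the transcription factor gene Etv4 by 1.76 ± 0.30. The sialyltransferase gene St8sia2 fell by 4.37 ± 0.38 (adjusted p = 0.000596). Mab21l3 (2.65 ± 0.47), Xaf1 (2.46 ± 0.47), Apln (2.30 ± 0.44) and Paox (1.37 ± 0.19) rose, and Pla2g2a (-4.88 ± 0.80), Rpl3-ps1 (-4.45 ± 0.90) and Ephx1 (-3.54 ± 0.56) fell. Il6ra (-0.52 ± 0.55), Axl (-0.32 ± 0.35), Inhbb (0.32 ± 0.37), Mdm2 (-0.47 ± 0.14), Socs3 (0.48 ± 0.34), Lgr5 (0.71 ± 0.67), Axin2 (-0.34 ± 0.39), Vim (-0.96 ± 0.29), Cdh1 (-0.10 ± 0.14), Mki67 (0.44 ± 0.26) and Myc (0.60 ± 0.18) did not pass.

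Of 27 core p53 targets 8 fell, 15 fell when adjusted over the list alone, and the median was -0.85 (camera adjusted p = 4.34e-12; adjusted p = 0.212 with an estimated correlation; fry adjusted p = 0.00253). The wider p53 list had 8 of 61 lower, 22 lower and 1 higher when adjusted over the list alone, and a median of -0.42 (camera adjusted p = 5.26e-09; adjusted p = 0.212 with an estimated correlation). Of 37 proliferation genes Cdc20 rose over all genes and 25 rose when adjusted over the list alone, with 36 above 0 and a median of 0.61 (camera adjusted p = 7.76e-17; adjusted p = 0.434 with an estimated correlation). DNA repair genes had a median of 0.42, with 0 of 29 passing limma's test over all genes, 7 at unadjusted p under 0.05 and 1 higher when adjusted over the list alone (camera adjusted p = 8.99e-07; adjusted p = 0.434 with an estimated correlation). Of the hypoxia and glycolysis genes (median 0.75) Slc16a3 rose, and 10 of 25 rose when adjusted over the list alone (camera adjusted p = 5.26e-09; adjusted p = 0.434 with an estimated correlation). Inflammatory genes had a median of 1.15, with 0 of 26 passing limma's test over all genes, 13 at unadjusted p under 0.05 and 9 higher when adjusted over the list alone (camera adjusted p = 2.27e-08; adjusted p = 0.434 with an estimated correlation). Their member Il6 was at 3.74 ± 0.88 (adjusted p = 0.0709).

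Of 32 colonocyte markers Aqp8 (-5.31 ± 0.84) and Saa1 (-3.40 ± 0.64) fell. Adjusted over the list alone 18 fell and 1 rose, and the median was -1.66 (camera adjusted p = 6.04e-09; adjusted p = 0.434 with an estimated correlation). Of 20 goblet markers Retnlb (-6.51 ± 0.96) and Tpsg1 (-2.82 ± 0.54) fell, 10 fell when adjusted over the list alone, and the median was -1.30 (camera adjusted p = 1.92e-06; adjusted p = 0.639 with an estimated correlation). Of 18 neutrophil markers Ngp rose by 3.74 ± 0.64 (not with a pseudocount of 0.1, adjusted p = 0.0894) and Ly6g fell by 1.58 ± 0.30. Adjusted over the list alone 4 rose and 1 fell, with a median of 0.99 (camera adjusted p = 0.000987; adjusted p = 0.639 with an estimated correlation). Mitochondrially encoded (median -0.63), cholesterol synthesis (0.36) and ribosomal protein genes (0.15) were called with no member passing limma's test over all genes or adjusted over the list alone and 4, 6 and 4 at unadjusted p under 0.05. Their camera adjusted p = 0.00101, 0.00127 and 0.0178; adjusted p = 0.801, 0.826 and 0.920 with an estimated correlation.

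By limma's test 193 of 21322 genes changed between double and miR-34a deficient tumours, 61 higher and 132 lower, and the groups did not overlap for 27.3% of genes (chance gives 10%). Under all 26 alternatives 7 of 30 named calls passed, namely Trp53, Ccng1, 9030617O03Rik (-2.47 ± 0.26), Fam212b, Fshr (-4.97 ± 0.32), St8sia2 and Tfrc. Cdkn1a passed under 15 (adjusted p up to 0.159), and without double deficient 3 only those 7 passed. The count of changed genes was 23 without double deficient 3, 42 without miR-34a deficient 2, 91 without double deficient 1, and 110 and 117 without miR-34a deficient 3 and 1. It was 57 with the removed direction, 73 with the Y-linked level and 86 with the run code as a covariate, and 79 without the libraries of the other run code. The ribosomal protein call was lost without miR-34a deficient 1 (adjusted p = 0.322) or double deficient 3 (0.0780), with the run code as a covariate (0.382) and without the libraries of the other run code (0.318), and the cholesterol call without miR-34a deficient 2 (0.0691) or double deficient 2 (0.137). The mitochondrial call was lost with quantile normalization (0.218) and with the Y-linked covariate (0.0692).

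**Figure D5:**
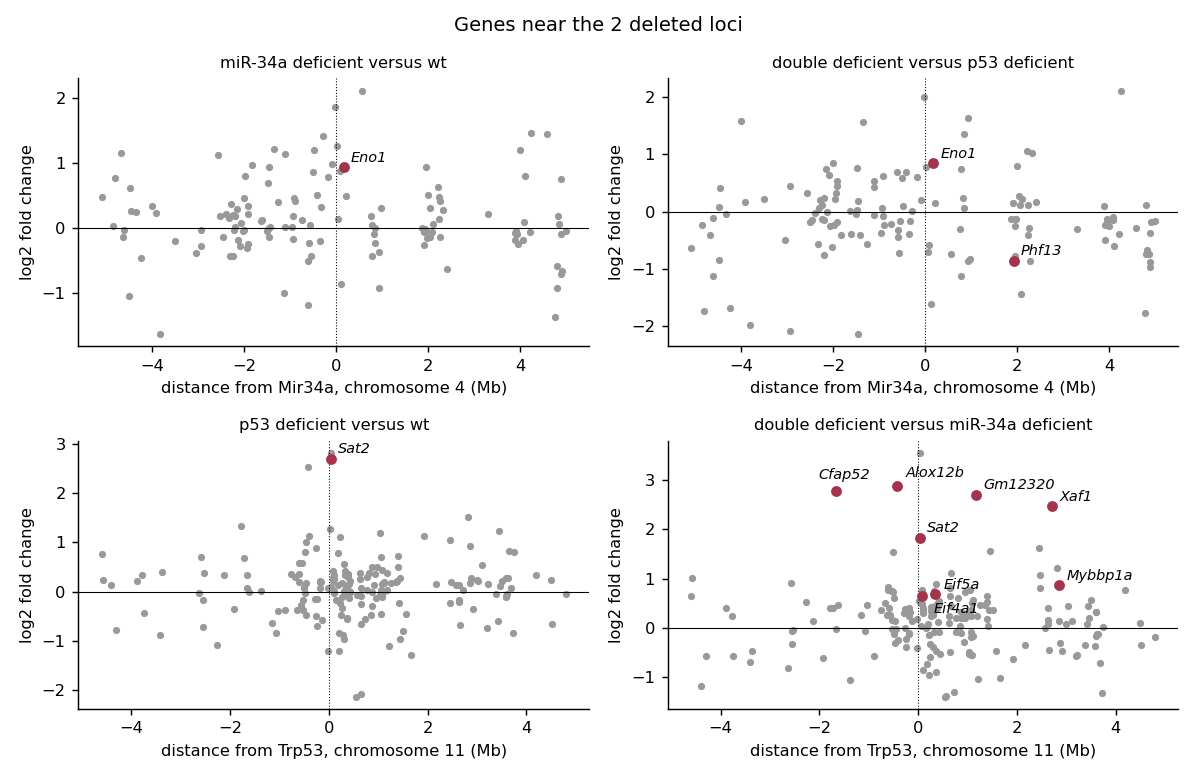
Log2 change (vertical axis) of genes within 5 Mb of the deleted gene against their distance from it in Mb (horizontal axis), in the 4 comparisons that differ at a single locus. Red labelled points are genes changed by limma's test and grey points the others, with the deleted gene left out. Eno1 beside Mir34a is at 0.93 and 0.85, and Sat2 beside Trp53 at 2.70 in p53 deficient tumours.

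The interaction of the 2 deletions, the change of double against p53 deficient tumours minus that of miR-34a deficient against wt tumours, asks whether loss of miR-34a acts differently without p53. Fshr (chromosome 17, 88984952 to 89200675) was the only named gene to pass, at -4.47 ± 0.46 (adjusted p = 0.00779). Its values were 2311, 2737 and 1286 in wt, 1187, 1701 and 1002 in miR-34a deficient, 1321, 1712 and 1264 in p53 deficient and 58, 33 and 32 in double deficient tumours. The other 4 changed genes, named after their values were seen, were the processed pseudogenes Gm15195 (-6.73 ± 0.51), Gm10093 (-4.79 ± 0.59) and Gm12196 (-4.42 ± 0.53) and the noncoding Gm7125 (-4.49 ± 0.59); Gm12196 lies near the floor of the values. Neither Il6ra (-0.12 ± 0.78), Cdkn1a (-0.76 ± 0.46) nor Il6 (2.69 ± 1.24) passed. Axl (0.21 ± 0.50), Inhbb (0.68 ± 0.53), Mdm2 (-0.36 ± 0.20), Ccng1 (-0.42 ± 0.25), Socs3 (0.14 ± 0.48), Lgr5 (1.95 ± 0.95), Axin2 (0.34 ± 0.55), Vim (0.06 ± 0.40), Cdh1 (-0.16 ± 0.19), Mki67 (-0.19 ± 0.37) and Myc (0.22 ± 0.25) did not pass either. The closest of the remaining genes were Gpr110 (-1.98 ± 0.30), Fam124a (-1.50 ± 0.23), Phactr4 (-1.47 ± 0.23), Ly6g (-2.48 ± 0.42), Pag1 (-1.77 ± 0.30), Ckap4 (0.78 ± 0.15), Paox (1.31 ± 0.27), Faah (1.02 ± 0.21) and Samd1 (1.20 ± 0.25), none of which passed.

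As lists, tuft cell (median 1.36), mast cell (1.35), Wnt target (0.65), inflammatory (0.62), macrophage and monocyte (0.45), proliferation (0.40), intestinal stem cell (0.34) and DNA repair genes (0.27) had a positive interaction. Their camera adjusted p = 0.00830, 0.00830, 0.00830, 0.00564, 0.0301, 3.38e-05, 0.0104 and 0.00830. Enteroendocrine (-0.81), goblet (-0.76), colonocyte (-0.62), smooth muscle (-0.42) and core p53 target genes (-0.34) had a negative one, with camera adjusted p = 0.00830, 0.0121, 0.00830, 0.0416 and 0.0320. None of the 13 calls held with an estimated correlation, where macrophage genes had adjusted p = 0.963 and each of the other 12 lists adjusted p = 0.956. No member passed limma's test over all genes, and adjusted over the list alone only 1 goblet marker did; at unadjusted p under 0.05 the most were 5 proliferation genes.

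By limma's test 5 of 21322 genes had an interaction, all negative, against 1683 at unadjusted p under 0.05, and only Gm15195 passed under all 24 alternatives that kept it. Fshr failed without the libraries of the other run code and with the Y-linked covariate (adjusted p up to 0.0676). The count was 10 without p53 deficient 1, 3 without miR-34a deficient 3 or double deficient 1, and 2 without wt 1, miR-34a deficient 2, p53 deficient 2 or 3, or double deficient 2 or 3. It was 2 with the removed direction and 1 with the Y-linked level as a covariate, and 3 with a replicate block. Every list call was lost without at least 1 library, and each of the 12 ended between 1 and 7 calls. The most were 7 without miR-34a deficient 2 (adjusted p up to 0.561), 7 without double deficient 1 (up to 0.577) and 5 without wt 2 (up to 0.199) or wt 3 (up to 0.451). The Y-linked covariate ended the p53 core, tuft, macrophage and mast cell calls (adjusted p up to 0.517), and the run code covariate those of stem cell, colonocyte, goblet, smooth muscle and macrophage genes (up to 0.561). Those 5 calls were also lost without the libraries of the other run code (up to 0.574).

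The sets changed against wt were also compared with each other, given that they share the wt libraries. Both p53 and double deficient tumours changed 5 genes in the same direction, Trp53, Ccng1, 9030617O03Rik, Fam212b and Sat2, and both miR-34a and double deficient tumours changed Eno1, Eno1b, Rpl35a and Gm4735. The 2 single deletions shared none. In 100 simulations with no effect of genotype, counted after the result was seen, p53 with double deficient shared at most 0 and miR-34a with double deficient at most 18, with 1 simulation sharing as many as observed. Independent sets of these sizes would share at most 0.0233 and 0.0291 in a direction, a value that leaves out the shared wt libraries. Those libraries may add to the excess for both pairs. The simulated sets had no effect of genotype and were not matched in size to the real ones. The counts shared in the simulations therefore cannot show how far the wt libraries add to the overlap. The sharing of Trp53 follows from the deletion that both groups carry. Sat2 lies 0.0417 Mb from Trp53 and Eno1 0.168 Mb from Mir34a. The covariance of all log2 changes was 0.215 for p53 with double deficient, 0.153 for miR-34a with double deficient and 0.0538 for the 2 single deletions. In 100 simulations with no effect of genotype the shared wt libraries alone gave 95% intervals of 0.00733 to 0.299, -0.0206 to 0.286 and -0.0419 to 0.310, which hold these values.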

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

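The tests and splits with the removed direction as a covariate, the splits between the 2 single deletions and the counts that take each gene near a locus once were chosen only after the result was seen; the others were set beforehand. The single-value models below were given the removed direction, and the Eno1 test its 95% interval requirement, after results were seen.

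The change on losing miR-34a differed between tumours with and without p53, by the interaction test, for Fshr (-4.465), Gm10093 (-4.788), Gm12196 (-4.416), Gm15195 (-6.731) and Gm7125 (-4.495). All 5 are low in every double deficient library; Fshr alone is protein coding, 3 are processed pseudogenes and Gm7125 is a lincRNA. The double deficient values of Gm12196 are 1, 0 and 0. In 4 of 100 drawn splits of the 12 libraries, the real one included, as many genes were called as in the real one. The real count is 5 and the highest other 692. Drawn splits mix the genotypes, so differences between genotypes can enter their interaction and raise its count. The missing direction sums to 0 within the real genotypes, which favours the real split. For both reasons the share of 4 in 100 decides nothing. With that direction as a covariate in every fit the real count is 2 and the highest other 89. As many genes were then called in 5 of 100 splits, the real one included. Chance is therefore not excluded, but these draws mix the genotypes too and cannot measure it. With the Y-linked level as a covariate, and also without the libraries of the other run code, Gm15195 passed and the other 4 did not. Fshr was then at -4.90 ± 0.59 (adjusted p = 0.0676) and -4.56 ± 0.56 (adjusted p = 0.0556) against -4.47 ± 0.46 (adjusted p = 0.00779), so its call ended with a wider spread, not with a smaller change. No prediction was set for sex or the run code as the cause of these changes.

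Changed genes lie beside the deleted loci, mostly in 1 comparison. Over the 4 comparisons that differ at a single locus, 12 of 640 tests within 5 Mb were called (1.88%) against 313 of 82594 elsewhere (0.379%; odds ratio 5.02, 95% interval 2.55 to 8.96; one-sided Fisher exact p = 1.03e-05). Of the 12, 8 came from double against miR-34a deficient tumours at Trp53, and Eno1 and Sat2 were each counted in 2 comparisons, so these tests are not independent. Of the 8, Sat2 alone was also called in p53 deficient tumours against wt. Xaf1, also among the 8, lay lower in miR-34a deficient tumours than in wt without passing. Its rise need not come from the Trp53 locus. With each gene counted once per locus, 10 of 320 were called (odds ratio 4.31, one-sided Fisher exact p = 0.000193), at Trp53 8 of 186 (Fisher exact p = 0.000297) and at Mir34a 2 of 134 (Fisher exact p = 0.202). DNA of another strain, or a local effect, carried along with the deleted alleles is a candidate explanation, and these values do not separate it from the loss of the gene itself. For Eno1, reads shared out differently with Eno1b were tested on the sum of the pair, which changed by 0.293 (SE 0.135, 95% interval -0.03 to 0.61) in miR-34a deficient and by 0.47 (0.15 to 0.80) in double deficient tumours. The first change exceeds 2 SE, which under the rule set beforehand counted against shared reads. Its 95% interval, required only after results were seen, holds 0, so the explanations of Eno1 cannot be told apart there. The interval in double deficient tumours lies above 0, but no prediction was set for them.

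Colonocyte markers were lower in double deficient tumours than in wt, with a mean change of -1.98 ± 0.44 (95% interval -3.02 to -0.95). With the Y-linked level as a covariate it was -2.23 (-3.33 to -1.13), which argues against sex as the whole cause. With the level of posterior Hox genes as a covariate it was -1.86 (-3.03 to -0.69). The Hox level spread most within the p53 deficient group, from 8.40 in p53 deficient 2 to 15.6 in p53 deficient 1. That group therefore mainly sets the adjustment, and the test cannot decide on position along the colon. The junction list, at -0.18, lay above the colonocyte list by 1.82 (0.81 to 2.83), which argues against fewer epithelial cells alone. A biological explanation, a lower state of differentiation, was not tested.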

How the results depend on the processing

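The removed direction, the Y-linked level and the X and Y genes were chosen after seeing the data. Except where a setting uses fewer libraries, the cause was not tested. Depth is unknown, so its effect on the results could not be tested. Not run: a count test and limma-voom (the values are not counts), and library weights, tried after seeing the data, whose estimation stopped early at 111 for double deficient 3. Counts follow the order miR-34a, p53 and double deficient against wt, double against p53, double against miR-34a, interaction. Of 165 named gene calls none reversed: in 4270 fits 2998 were called again and 1272 were not. The settings differed widely in this. With the removed direction as a covariate 68 of the 165 were called again and 97 were not. With the Y-linked level 46 were called again and 119 were not. Sign changes under 1 SE of uncalled genes counted as the same (70 fits of 30 results).

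Genes changed numbered 5, 2, 57, 47, 57 and 2 with the removed direction, 5, 1, 80, 7, 73 and 1 with the Y-linked level, and 17, 144, 451, 346, 768 and 10 at adjusted p under 0.10. Quantile normalization gave 5 for miR-34a deficient against wt. Only the 2 groups gave 1, 88 and 12 for p53 and double against wt and double against p53; a replicate block gave 2, 102 and 3 for p53 and double against wt and the interaction. Without the other run code's libraries p53 and double against wt and double against miR-34a gave 8, 74 and 79; with the run code as a covariate the last gave 86. Shared genes at 0.10 were 39 for p53 and double and 1 for the single deletions. Without 1 library the counts ranged 4 to 12, 1 to 88, 29 to 261, 27 to 294, 23 to 246 and 2 to 10.

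Lists called numbered 15, 13, 17, 14, 12 and 13. With an estimated correlation there were 0, 0, 0, 0, 0 and 0 (camera), with directional fry 0, 2, 4, 0, 2 and 0, and with mixed fry 1, 5, 12, 8, 13 and 0. The Y-linked level gave 8 for p53 against wt. Without 1 library they ranged 11 to 20, 10 to 15, 14 to 21, 10 to 20, 11 to 17 and 6 to 14. The seed site difference ranged 0.02 to 0.06 and -0.04 to -0.02.

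Uncalled genes that changed sign, with the range without 1 library: miR-34a against wt Cdkn1a -0.35 (without wt 3) to 0.44, Ccng1 -0.068 (without wt 3) to 0.27, Mki67 -0.32 to 0.18 (without wt 3), Il6 -1.29 to 0.41 (without miR-34a deficient 1; also 0.41 without the other run code). In p53 against wt Il6ra ran -0.90 to 0.17 (without wt 2). Socs3, p53 deficient versus wt, ran -0.0026 (without p53 deficient 3) to 0.64 and was -0.069 with the Y-linked level. Vim in double against wt ran -0.59 to 0.033 (without wt 2). Quantile normalization gave Cdh1 0.20, 0.070, 0.30 and 0.18 in the last 4 comparisons listed. With the Y-linked level Mki67 was 0.071 in double against p53 and 0.19 in the interaction.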

Other observations

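The comparison of p53 with miR-34a deficient tumours, its splits and the test with the removed direction were chosen after the result was seen; the tests of the run code and of sex were set before their results were.

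Between p53 and miR-34a deficient tumours 722 of 21322 genes changed by limma's test, 242 higher and 480 lower, more than either differed from wt. The count was 108, 152 and 41 without miR-34a deficient 1, 2 and 3, 1267, 191 and 90 without p53 deficient 1, 2 and 3, 218 without double deficient 3 and 37 with only the 2 groups in the fit. Wnt target genes had a median of -1.19, with 9 of 26 lower, among them Wif1 (-3.62 ± 0.53), and adjusted over the list alone 13 lower and 4 higher (camera adjusted p = 0.000669; adjusted p = 0.692 with an estimated correlation). Proliferation genes had a median of 0.64, with 4 of 37 higher and 22 when adjusted over the list alone (camera adjusted p = 3.78e-15; adjusted p = 0.602 with an estimated correlation). Vim fell by 1.69 ± 0.29, and all 26 fibroblast and matrix genes lay below 0 with none passing over all genes or over the list alone (median -0.84, 5 lower at unadjusted p under 0.05; camera adjusted p = 0.000601; adjusted p = 0.692 with an estimated correlation). Of 56 named calls 5 passed under all 26 alternatives, namely Trp53, Ccng1, 9030617O03Rik, Fam212b and Eno1b. None of these is a proliferation gene or a Wnt target gene of the lists, so the member counts above depend on the setting. Wif1 passed under 23 (adjusted p up to 0.0774), not with only the 2 groups, the Y-linked covariate or without miR-34a deficient 3. Vim passed under 20 (adjusted p up to 0.0907), not with the Y-linked covariate, without the libraries of the other run code, or without miR-34a deficient 1 or 3 or p53 deficient 2 or 3.

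The count was 147 with the removed direction as a covariate, 366 without the libraries of the other run code and 27 with the Y-linked level as a covariate. Each is more than 2 times the larger count against wt in the same fit. Those counts against wt were at most 8, so this ratio is passed easily and decides nothing about the cause. Of the 722 calls, 147 held with the removed direction as a covariate and 269 without the libraries of the other run code. Too small a spread and the run code may thus each be part of the cause, while neither setting ended every call. With the Y-linked level the count fell from 722 to 27. The Y-linked level is graded, at 0, 2.77 and 5.28 in miR-34a deficient and 3.73, 5.21 and 6.98 in p53 deficient libraries. Sex may therefore contribute to the count of 722. The biological explanation, that the 2 deletions move the same genes in opposite directions, was not tested.

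The splits of the same 6 libraries number 10 with the real one, too few for a share under 0.05. In 1 of 10, the real split alone, as many genes were called in each comparison. The missing direction sums to 0 within the real genotypes, which favours the real split, and these splits were not run with it as a covariate. The other splits also hold differences between genotypes in their spread. The counts therefore decide nothing about chance. The real and the highest other counts were 8 and 0 for miR-34a deficient against wt, 5 and 1 for p53 deficient against wt, 171 and 0 for double deficient against wt, 129 and 0 for double against p53 deficient, 193 and 2 for double against miR-34a deficient, and 722 and 0 for p53 against miR-34a deficient tumours.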
